A study of Drosophila melanogaster with 46 samples.

How the data were processed

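Chromatin from whole Drosophila melanogaster, wild-type or mutant larvae or wild-type adults, was immunoprecipitated for CTCF, Pita, Su(Hw) or CP190 and sequenced, per the labels. CTCF carried an HA tag and was precipitated with an antibody against it, per the labels' protocols. The protocol text describes chromatin from larvae only, although some samples are labelled adult, and it lists a rat antibody against CP190 while the wild-type CP190 samples are labelled with one from rabbit. Per the submitters' processing notes the genome build was dm6 and the tools included cutadapt, Bowtie2, Picard, bedtools, MACS2 and deepTools, with no roles, order or versions given in the sources used here.

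The deposited files are 7 peak lists with 20 columns per peak, in the layout of an IDR comparison of 2 input lists. Which samples made each input is not given in the sources used here, so replicates could not be compared and no depth per sample was known. The authors' deposited values per peak are a fold enrichment, a linear ratio over a control that is not named, the −log10 p and −log10 q of the peak as deposited, and the −log10 p of the peak in each input list. The deposited score column was checked for every peak of the 7 lists and equals 125 times −log2 of the global IDR, rounded down and capped at 1000. Median second-to-first ratios of −log10 p between the inputs were 1.85 in the larval Pita list and 2.12 in the adult Su(Hw) list, and from 1.00 to 1.005 in the others. The authors' fold enrichment was used to describe and rank peaks, and its log2 to test differences between peaks of 1 list. The stratification by the highest fold at a site is the exception that sets folds of the 3 C2H2 lists side by side, and ranks of fold within each list were used in its place as an alternative.

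Groups were taken from sample titles. The CP190 list names no genotype and was used as the larval CP190 list, and as 14 of the 18 CP190 samples are from mutant larvae it may hold peaks of mutant larvae. The other lists are named as wild type. Mutant and wild-type larvae could not be compared, since no list is named for a mutant. Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used, and peaks on other sequences were counted apart. Peaks of 2 lists were shared when they overlapped by at least 1 bp. Larval C2H2 peaks joined by such overlaps made a site, which carried CP190 when any of its peaks overlapped a CP190 peak. Shares have exact Clopper-Pearson 95% intervals, odds ratios Woolf 95% intervals, and intervals cover counting error only. Overlaps were set against 1000 random relocations of the first list within its chromosomes. Two-sided Fisher exact tests compared shares, permutation tests with 100000 resamples compared medians of log2 fold, and p-values were adjusted by Benjamini-Hochberg within each family. The threshold was 0.05.

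Gene positions came from the RefSeq gene table of the Release 6 plus ISO1 MT assembly, the same assembly as dm6, with 17807 genes on these chromosomes, of which 13946 are protein-coding. The table gives no strand, so the planned distance to a transcription start was replaced by the distance to either end of a gene, within 500 bp. A gene was near a peak when either of its ends lay within 500 bp of the peak. A peak is said to be within a gene when its summit, or the middle of a site, lies in the gene's span, and otherwise near the gene with the closest end. The 13 gene lists were tested in each peak list, against all other protein-coding genes or, for tRNA genes, all other genes. All members named singly were found in the table. Lists taken by the start of a symbol also hold Cpr and Vmat, which encode no cuticle or vitelline protein. No genome sequence was used here, so the planned search for sequence words under the summits was not run.

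The tests, the gene lists, the rule for named peaks and all alternatives not marked otherwise were chosen before the data were examined. Named are the 5 highest peaks of each list, the 10 sites with all 4 proteins and the highest CP190 fold, the peaks of both Hox complexes summarised with the highest per list, the 3 strongest peaks of each larval list without CP190, the 3 strongest peaks per protein and stage without a partner at the other stage, up to 4 members of each gene list that passed, and the genes of the 4 proteins. Of these, 1 member of a gene list that this rule names is not reported here. The 10 strength classes, and the tests of each pair of proteins against its members, were chosen after seeing the data. Classes for the IDR rank peaks by −log10 p in the first input list, and classes for shares with a partner rank them by fold.

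The alternatives were overlap of at least 0.5 of the shorter peak, summits within 200 bp, peaks at or above the median −log10 q of their list, and autosome arms only. Others were relocations matched on distance to a gene end, stratification by quartile of fold, C2H2 lists cut to equal length by −log10 q, and gene distances of 200 and 1000 bp. The CP190 list was not cut for equal length. Chosen after seeing the data were distances to gene ends in place of transcription starts, an IDR of at most 0.01 in every list, leaving out the strongest 10% of each C2H2 list, stratification by nearness to a gene end or by quartile of the highest rank of fold within its list, and gene lists without Cpr and Vmat. The procedures were tested on simulated data, 20 times each. A planted overlap of a list of about 1000 sites with a longer list was recovered and passed in 20 of 20 runs, and unrelated lists passed in 1. These lists lay on the autosome arms only, and fewer relocations than the 1000 used for the data were run. For CP190 share by number of proteins, simulated with 4970 sites and an odds ratio of 4 with a confounder of strength, the stratified estimate averaged 4.05 and the unstratified one 6.01. The simulated confounder was constant within each stratum, so strength that differs within a quartile was not simulated. A gene list with 30 seeded members among 17807 genes was called in 20 of 20 runs, with 2 false calls in 260 unseeded tests. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.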

Results

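The data are chromatin immunoprecipitation sequencing (ChIP-seq) peaks of 4 Drosophila proteins from whole animals. CTCF, Pita and Su(Hw) are DNA-binding proteins with clusters of C2H2 zinc fingers, known as architectural or insulator proteins. CP190 is a BTB-domain protein found at insulators and promoters that such proteins can bind, and the series title names its recruitment by cooperating C2H2 proteins as the subject. The labels list 46 samples in 15 groups, with 4 wild-type larval samples each for CTCF and CP190, and 2 samples each for larval Pita, larval Su(Hw), adult CTCF, adult Pita and adult Su(Hw). A further 28 samples in 8 groups come from larvae with mutations in the CP190-binding domain of CTCF, alone or with such mutations in Pita, Su(Hw) or both, and no list is named for them. The 7 lists used are the authors' deposited peaks, laid out as a comparison of 2 input lists that are not tied to samples, so a peak has 1 value and no error between replicates. The name of the CP190 list gives the stage and no genotype. Of the 18 CP190 samples 14 are from mutant larvae, so the list may mix genotypes, and every CP190 value below is for larvae of unstated genotype set against wild-type lists of the C2H2 proteins. All positions are on the dm6 genome build.

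The larval lists on the main chromosome arms held 808 CTCF peaks, 1213 Pita peaks, 3374 Su(Hw) peaks and 4220 CP190 peaks, and the adult lists 674 CTCF, 1498 Pita and 3115 Su(Hw) peaks. Median fold enrichment over the authors' control ranged from 5.01 in the CP190 list to 11.3 in the adult CTCF list. Read depth is not given by a peak list and is unknown here. Each peak carries a global irreproducible discovery rate (IDR). It estimates the share not reproducible between 2 input lists among all peaks at least as reproducible as that peak. The highest IDR was 0.01 in 5 lists and 0.05 in the larval Pita and adult Su(Hw) lists. Peaks were ranked here by −log10 p in the first input list. In the larval Pita and both Su(Hw) lists the median −log10 IDR of the strongest 10% of peaks was at or above that of the next 10%. In the CP190, adult CTCF, larval CTCF and adult Pita lists it fell at the top, from 2.79 to 2.68, from 2.17 to 2.11, from 2.65 to 2.56 and from 2.46 to 2.38. The strongest CP190 peak by the same ranking had a −log10 IDR of 2.0, which is also the lowest of its list. Signal at sites absent from a list was not analysed here.

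**Figure D1:**
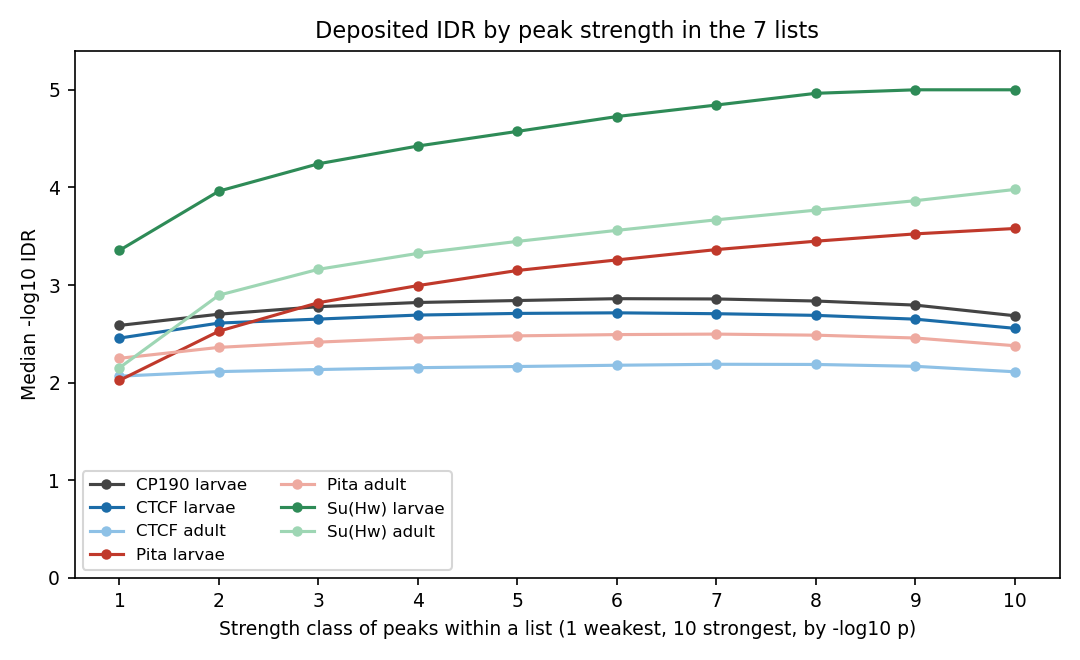
Median −log10 IDR (y axis) of the peaks of each of the 7 lists in 10 classes of strength by −log10 p in the first input list (x axis, 1 weakest). The line for larval Su(Hw) rises to 5.00, while those for CP190, larval CTCF, adult CTCF and adult Pita turn down to 2.68, 2.56, 2.11 and 2.38 in the strongest class.

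The highest CP190 peak, 70.2-fold enriched, covered bases 7097615 to 7098817 of chromosome X, 112 bp from an end of Sxl, the switch gene of sex determination. It overlapped a Pita peak of 50.5-fold in larvae. The next 4 CP190 peaks lay near CG10232 (66.9-fold), at UQCR-Q (66.7-fold), a subunit of the mitochondrial respiratory chain, within dysc (65.6-fold) and within Svil (65.5-fold). The CG10232 site carried CTCF, the UQCR-Q site Pita, the dysc site Su(Hw), and the Svil site CTCF and Pita. The 5 highest larval CTCF peaks lay near nAChRalpha5 (184-fold), a nicotinic acetylcholine receptor subunit, near Wdr62 (179-fold) and CR31958 (174-fold), at CG33557 (172-fold) and within Antp (171-fold). In adults they lay near bcd (251-fold), the anterior determinant, Uhg5 (205-fold) and bor (204-fold), within Abd-B (201-fold), and near lov (199-fold). The highest larval Pita peaks were near Rala (122-fold), a small GTPase, sfl (113-fold), needed for heparan sulfate synthesis, within nemy (109-fold), and near brn (109-fold) and CG6073 (104-fold). In adults they were near CG13323 (118-fold) and brn (118-fold), within klar (114-fold), at UQCR-Q (114-fold), a site also among the 5 highest of CP190, and near CG7655 (110-fold). Su(Hw) shared 2 of its 5 highest peaks between the stages. These were an intergenic site on chromosome 4, at 415428 to 416395 in larvae, with 115-fold in larvae and 119-fold in adults, and a site inside the gene twi with 93.6-fold and 107-fold. Its other highest peaks were near Loxl1 (106-fold), within mwh (95.5-fold) and near upd2 (95.3-fold) in larvae, and within CCKLR-17D3 (135-fold) and CG44837 (99.4-fold) and near CG13707 (97.4-fold) in adults.

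The first comparison asked how often larval sites of each C2H2 protein carried CP190. Of the larval Pita peaks 70.7% overlapped a CP190 peak (858 of 1213, exact 95% interval 68.1% to 73.3%). The share was 59.8% for CTCF (483 of 808, 56.3% to 63.2%) and 34.9% for Su(Hw) (1179 of 3374, 33.3% to 36.6%). Peaks moved at random within their chromosomes overlapped CP190 in 5.80%, 5.65% and 5.17% of cases on average, so the observed shares were 12.2, 10.6 and 6.76 times higher. No relocation of 1000 reached the observed share in any of the lists (one-sided permutation p = 0.001, the smallest this number can give). The unit of this and the following tests is a site in these lists, so the p-values describe the lists and not the spread between animals.

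Sites that carried only 1 of the C2H2 proteins kept this order. CP190 was found at 66.4% of 897 Pita-only sites (exact 95% interval 63.3% to 69.5%), 50.7% of 527 CTCF-only sites (46.3% to 55.0%) and 32.0% of 3150 Su(Hw)-only sites (30.4% to 33.7%). The odds of CP190 at Pita-only sites were 1.93 times those at CTCF-only sites (two-sided Fisher exact test, Benjamini-Hochberg adjusted p = 4.86e-09 over 3 tests) and 4.20 times those at Su(Hw)-only sites (adjusted p = 2.07e-75). CTCF-only sites had 2.18 times the odds of Su(Hw)-only sites (adjusted Fisher exact p = 6.57e-16). Each C2H2 list was also cut to its 674 most significant peaks, which changes both its length and the strength of its peaks. The CP190 list was kept whole. Then 69.9% of Su(Hw) peaks and 63.5% of CTCF peaks carried CP190, and the odds ratio of CTCF-only against Su(Hw)-only sites turned to 0.638 (adjusted Fisher exact p = 3.82e-04). The same lists gave odds ratios of 4.31 for Pita-only against CTCF-only sites (adjusted Fisher exact p = 6.12e-23) and 2.75 for Pita-only against Su(Hw)-only sites (adjusted p = 1.70e-11).

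The C2H2 proteins shared sites more often than chance relocation gave. Larval CTCF and Pita shared the most, with 198 CTCF peaks (24.5%, exact 95% interval 21.6% to 27.6%) on a Pita peak against 15.2 on average after relocation, a ratio of 13.0. For CTCF and Su(Hw) 104 CTCF peaks (12.9%, 10.6% to 15.4%) were shared against 37.0 by relocation, a ratio of 2.81. For Pita and Su(Hw) 137 Pita peaks (11.3%, 9.57% to 13.2%) were shared against 56.9, a ratio of 2.41. The one-sided permutation p was 0.001 for each pair, the smallest possible. Over the alternatives the ratio ranged from 6.92, with relocated peaks kept at their distance to the nearest gene end, to 53.6, with summits within 200 bp, for CTCF and Pita. It ranged from 2.32 to 9.29 for CTCF and Su(Hw) and from 2.25 to 6.96 for Pita and Su(Hw), highest with summits within 200 bp in both.

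Sites with more than 1 C2H2 protein carried CP190 more often, which is the comparison the series title points to. A site carried CP190 when any of its peaks overlapped a CP190 peak, so more peaks gave a site more chances. The share that this rule alone would give was not computed. CP190 was present at 87.0% of 115 sites with Pita and Su(Hw) (exact 95% interval 79.4% to 92.5%), 83.3% of 174 sites with CTCF and Pita (77.0% to 88.5%) and 68.7% of 83 sites with CTCF and Su(Hw) (57.6% to 78.4%). The 24 sites with all 3 proteins had CP190 in 15 cases (62.5%, 40.6% to 81.2%). Together 80.1% of the 396 sites with 2 or 3 proteins carried CP190 against 40.9% of the 4574 sites with 1 protein, an odds ratio of 5.79 (95% interval 4.50 to 7.46, two-sided Fisher exact test p = 1.50e-52). Since 3150 of the sites with 1 protein are Su(Hw) sites, each pair was also set against its own members, a test chosen after seeing the data. CTCF and Pita sites had 4.87 times the odds of CTCF-only sites (adjusted p = 1.12e-14 over 6 tests) and 2.53 times those of Pita-only sites (adjusted p = 7.31e-06) by Fisher's exact test. Pita and Su(Hw) sites had 3.37 times the odds of Pita-only sites (adjusted Fisher exact p = 4.68e-06) and 14.1 times those of Su(Hw)-only sites (adjusted p = 2.83e-32). CTCF and Su(Hw) sites had 4.65 times the odds of Su(Hw)-only sites (adjusted Fisher exact p = 3.85e-11) and 2.13 times those of CTCF-only sites (adjusted p = 0.00292). Within quartiles of the highest fold at a site the odds ratio of 2 or 3 against 1 protein was 2.53 (95% interval 1.93 to 3.32). These quartiles compare fold between lists, and within quartiles of the highest rank of fold in its own list, chosen after seeing the data, it was 2.99 (2.29 to 3.91). In the more significant part of each list, at or above its median −log10 q, pairs no longer passed against CTCF-only sites (odds ratios of 1.95 with Pita and 1.34 with Su(Hw)) or Pita-only sites (1.11 with CTCF and 1.31 with Su(Hw)), with adjusted Fisher exact p from 0.128 to 0.869. CTCF and Su(Hw) sites also missed the threshold against CTCF-only sites on the autosome arms (1.80, adjusted Fisher exact p = 0.0590) and within quartiles of fold (1.54, Mantel-Haenszel adjusted p = 0.0978). The other pair tests passed within quartiles of fold. CTCF and Pita sites gave 5.69 against CTCF-only and 1.71 against Pita-only sites. Pita and Su(Hw) sites gave 3.45 against Pita-only and 9.81 against Su(Hw)-only sites. CTCF and Su(Hw) sites gave 3.92 against Su(Hw)-only sites.

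**Figure D2:**
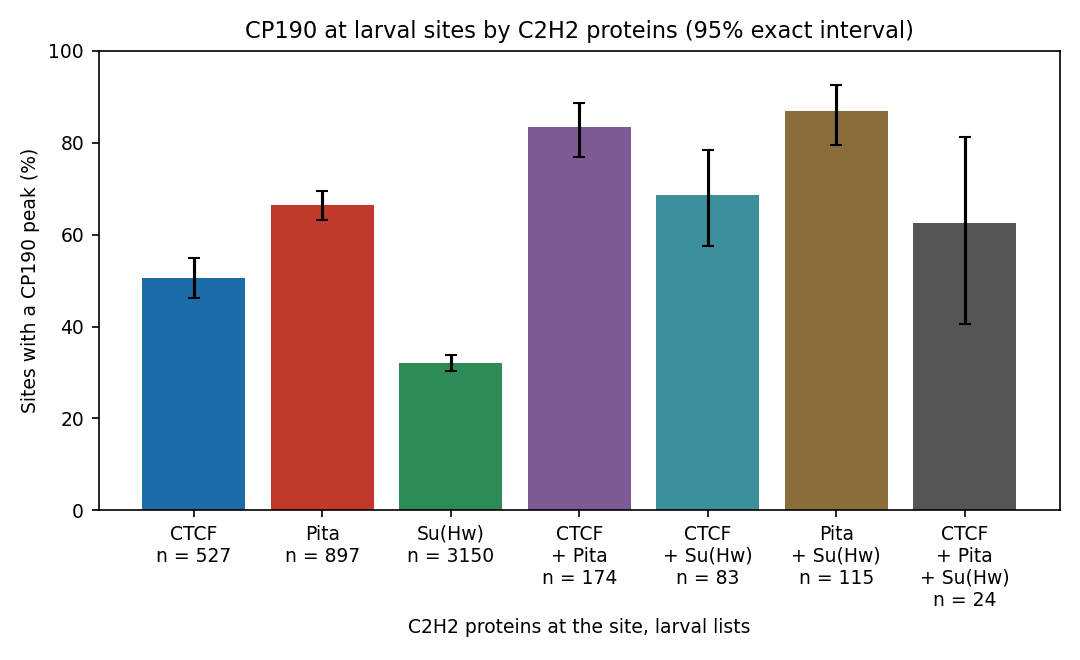
Share of larval sites with a CP190 peak (y axis, %) by the C2H2 proteins at the site (x axis, with the number of sites), with exact 95% intervals as error bars. Sites with Pita and Su(Hw) reach 87.0% and those with CTCF and Pita 83.3%, above the 66.4%, 50.7% and 32.0% of Pita, CTCF and Su(Hw) alone.

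The CP190 peaks themselves were higher where more C2H2 proteins were present. The 2012 CP190 peaks without a C2H2 peak had a median fold of 3.59 (quartiles 2.77 and 5.19), the 1889 with 1 protein 8.50 (4.21 and 17.3), the 305 with 2 proteins 16.3 (8.03 and 32.4) and the 14 with 3 proteins 30.3 (18.7 and 39.2). The difference in median log2 fold was 0.96 between 2 or 3 proteins and 1, and 1.41 between 1 or more and none (two-sided permutation p = 1.00e-05 for both, the smallest that 100000 permutations can give). Of the 15 sites with all 4 proteins, the 10 with the highest CP190 fold included a site within chas (CP190 64.4-fold), an intergenic site whose nearest gene end was that of Act88F (62.9-fold), the flight muscle actin gene, and sim (59.5-fold), the midline regulator, at bases 13077250 to 13078957 of 3R. The others were within NaPi-III (40.0-fold), Appl (39.7-fold), bin (36.8-fold), shot (33.2-fold), Pc (30.3-fold), the founding Polycomb gene, Diap1 (30.2-fold), an inhibitor of apoptosis, and drd (23.4-fold). At the chas site, bases 17694548 to 17696790 of X, the larval folds were 130 for CTCF, 32.4 for Pita and 18.2 for Su(Hw). At Pc they were 2.17, 17.0 and 2.33.

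CP190 went with stronger C2H2 peaks. Larval CTCF peaks with CP190 had a median fold of 26.8 against 3.29 without it, Pita peaks 8.06 against 2.93 and Su(Hw) peaks 11.3 against 5.27. These are differences of 3.02, 1.46 and 1.10 in median log2 fold (two-sided permutation p = 1.00e-05 each, the smallest possible). From the weakest to the strongest quartile of fold, the share of Su(Hw) peaks with CP190 rose from 13.6% to 22.5%, 38.4% and 65.2%. For CTCF the quartiles gave 38.1%, 33.2%, 80.7% and 87.1%, and for Pita 44.7%, 67.0%, 87.8% and 83.5%. Among peaks at or above the median −log10 q the differences were smaller, with 1.67 for CTCF and 0.65 for Su(Hw) (permutation p = 1.00e-05 each) and 0.19 for Pita, which did not pass (permutation p = 0.217).

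Some of the strongest C2H2 peaks had no CP190 peak. For CTCF these were the peaks near nAChRalpha5 (184-fold, bases 14093985 to 14096108 of 2L) and Wdr62 (179-fold) and within Antp (171-fold). For Pita they were near Rala (122-fold, bases 3719098 to 3720491 of X), brn (109-fold) and CG6073 (104-fold). For Su(Hw) they were the intergenic chromosome 4 site (115-fold), Loxl1 (106-fold) and the site in mwh (95.5-fold). In the strongest 10% of larval CTCF peaks 71.6% carried CP190 (58 of 81, exact 95% interval 60.5% to 81.1%) against 96.3% of the next 10% (78 of 81, 89.6% to 99.2%). For larval Pita the shares were 74.6% and 90.1%, whereas for larval Su(Hw) they were 77.2% and 62.0%. The CP190 list is 1 of those whose −log10 IDR fell at its strongest peaks.

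The stage comparison asked which larval peaks were also in the adult list of the same protein. For Su(Hw) 86.9% of larval peaks were in the adult list (2932 of 3374, exact 95% interval 85.7% to 88.0%) and 93.7% of adult peaks were in the larval list. For Pita 84.7% of larval peaks (1028 of 1213, 82.6% to 86.7%) and 69.8% of adult peaks were shared. For CTCF 69.4% of larval peaks (561 of 808, 66.1% to 72.6%) and 84.3% of adult peaks were shared. The odds of an adult partner were 2.92 times higher for larval Su(Hw) than for CTCF peaks (two-sided Fisher exact test, adjusted p = 5.10e-29 over 3 tests) and 2.45 times higher for Pita than for CTCF (adjusted p = 5.62e-16). The odds ratio of Su(Hw) against Pita was 1.19 (adjusted Fisher exact p = 0.0641). With lists of equal length Su(Hw) and CTCF no longer differed past the threshold (1.32, adjusted Fisher exact p = 0.0852). Su(Hw) against Pita turned to 0.450 among peaks at or above the median −log10 q of their list (adjusted Fisher exact p = 5.81e-07) and to 0.651 with an IDR of at most 0.01 in every list, a setting chosen after seeing the data (adjusted p = 2.78e-05). It ranged from 0.450 to 1.19 over the alternatives, and the odds ratio of Pita against CTCF from 1.63 to 3.82.

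The strongest adult CTCF peaks without a larval CTCF peak were those near bcd (251-fold, bases 6759292 to 6760186 of 3R), Uhg5 (205-fold) and bor (204-fold). The bcd site carried a larval CP190 peak of 53.9-fold, and the bor site a larval Pita peak of 11.8-fold. The strongest larval CTCF peaks without an adult one were near nAChRalpha5 (184-fold), CheB93a (147-fold) and CG7029 (37.6-fold). For Pita the larva-only peaks were near Rala (122-fold), sfl (113-fold) and within nemy (109-fold), and the adult-only peaks within CG12054 (63.3-fold) and near CG43759 (40.0-fold) and Reg-2 (31.6-fold). For Su(Hw) the highest stage-restricted peaks were within sima (7.62-fold), CG42674 (7.37-fold) and Alp7 (6.68-fold) in larvae, and within Pzl (17.7-fold) and CG42795 (11.0-fold) and 51 bp from an end of the chorion gene Cp15 (10.4-fold) in adults. In the strongest 10% of adult CTCF peaks 69.1% had a larval partner (47 of 68, exact 95% interval 56.7% to 79.8%) against 98.5% of the next 10% (66 of 67). For larval Pita peaks in the adult list the values were 75.4% and 99.2%. Larval CTCF peaks in the adult list changed less, with 97.5% in the strongest 10% against 100% of the next 10%. The shares were 99.3% and 98.0% for adult Pita peaks in the larval list, and 100% in the strongest 10% of both Su(Hw) lists. Both CTCF lists and the adult Pita list are among those whose −log10 IDR fell at the top, and the signal at these places in the other stage was not analysed here.

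**Figure D3:**
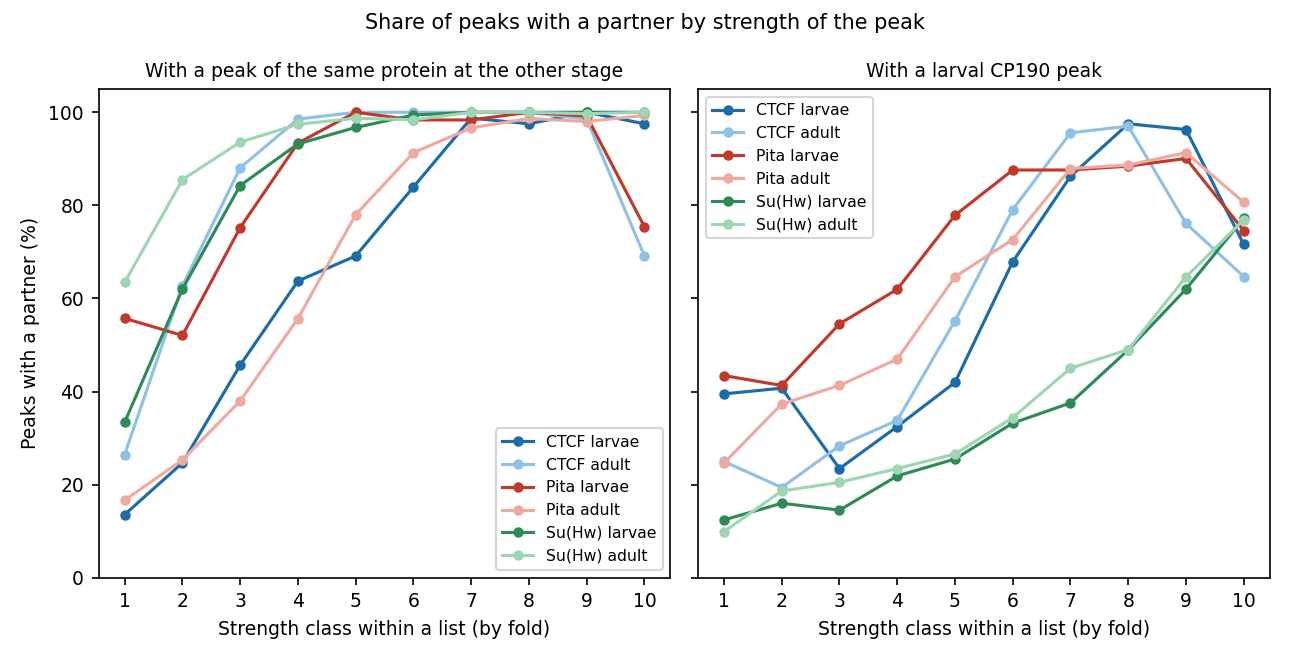
Share of peaks with a partner (y axis, %) in 10 classes of fold enrichment within each list (x axis, 1 weakest), for a peak of the same protein at the other stage (left) and a larval CP190 peak (right). Shares are lowest among weak peaks, and from the ninth to the strongest class they fall to 69.1% for adult CTCF and 75.4% for larval Pita on the left and to 71.6% for larval CTCF on the right, while larval Su(Hw) rises to 77.2%.

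Larval peaks found at both stages carried CP190 more often than larva-only peaks. For Pita the shares were 75.6% of 1028 and 43.8% of 185 peaks, an odds ratio of 3.97 (adjusted p = 1.16e-16, two-sided Fisher exact test over 3 proteins). For CTCF they were 64.5% of 561 and 49.0% of 247, an odds ratio of 1.89 (adjusted Fisher exact p = 4.88e-05). For Su(Hw) they were 38.5% of 2932 and 11.5% of 442, an odds ratio of 4.79 (adjusted Fisher exact p = 3.78e-32). These comparisons did not hold peak strength equal. For all 3 proteins an adult partner and CP190 were both more frequent in the strongest class of fold than in the weakest. For larval CTCF the share with an adult partner was 13.6% in the weakest class and 97.5% in the strongest. Its share with CP190 was 39.5% and 71.6%. Whether the difference between stages holds at equal strength was not tested. With equal-length lists the Su(Hw) odds ratio was 1.01 (adjusted Fisher exact p = 1.00), while Pita (2.61) and CTCF (1.99) still passed.

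CP190, Pita and CTCF lay near gene ends more often than Su(Hw). The summit was within 500 bp of either end of an annotated gene for 70.9% of CP190 peaks (exact 95% interval 69.5% to 72.2%), 66.2% of larval Pita peaks (63.5% to 68.9%), 50.6% of larval CTCF peaks (47.1% to 54.1%) and 20.6% of larval Su(Hw) peaks (19.3% to 22.0%). Adult lists gave 61.7% for Pita, 50.7% for CTCF and 20.5% for Su(Hw). The share expected for random positions was not computed, so these shares compare the lists with each other only. Peaks with CP190 were near a gene end more often than those without it for Su(Hw) (36.9% against 11.9%, odds ratio 4.33, adjusted p = 2.13e-62), CTCF (62.5% against 32.9%, 3.40, adjusted p = 2.44e-16) and Pita (73.4% against 48.7%, 2.91, adjusted p = 3.82e-16) by two-sided Fisher exact tests. At or above the median −log10 q the CTCF odds ratio was 1.43 and did not pass (adjusted Fisher exact p = 0.123). The gene table used here gives no strand, so starts and ends of genes were not separated, and exons, introns and untranslated regions were not assigned.

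Among 13 fixed gene lists, genes of the cytoplasmic ribosome stood out at CP190 and Pita sites. CP190 lay within 500 bp of an end of 74 of 93 ribosomal protein genes (79.6%) against 35.4% of other protein-coding genes, an odds ratio of 7.11 (adjusted p = 5.25e-16 over 91 tests, two-sided Fisher exact test). The highest of these CP190 peaks were at RpS27 (60.5-fold), RpS28a (59.9-fold), RpL30 (53.8-fold) and RpS14a (49.9-fold). Pita lay near 29 of them in larvae (31.2% against 10.3%, odds ratio 3.93, adjusted Fisher exact p = 1.15e-06) and 28 in adults (30.1% against 11.0%, 3.50, adjusted p = 8.92e-06). RpL17 (81.1-fold) and RpS10a (49.0-fold) led in larvae, followed by RpL30 (46.7-fold) and RpS14a (44.3-fold), and RpL17 (102-fold), RpL23 (90.1-fold) and RpS10a (89.1-fold) in adults. CP190 was also near 14 of 20 replication genes (70.0% against 35.6%, odds ratio 4.21, adjusted Fisher exact p = 0.0141), among them Mcm7 (19.9-fold), Orc2 (16.4-fold), dup (12.0-fold) and PCNA (9.26-fold). At or above the median −log10 q the replication genes no longer passed (2.43, adjusted Fisher exact p = 0.436).

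Chemoreceptor, cuticle protein and tRNA genes were less often near CP190, and the chemoreceptor and cuticle protein lists also less often near Pita. CP190 lay near 17 of 179 chemoreceptor genes (9.50% against 36.0%, odds ratio 0.186, adjusted p = 4.29e-14), 22 of 119 cuticle protein genes (18.5% against 35.8%, 0.406, adjusted p = 5.28e-04) and 53 of 290 tRNA genes (18.3% against 30.8% of all other genes, 0.502, adjusted p = 2.68e-05) by Fisher's exact test. At or above the median −log10 q the cuticle protein (0.697, adjusted Fisher exact p = 0.669) and tRNA genes (0.758, adjusted p = 0.589) no longer passed for CP190. The tests took genes as independent, although neighbouring genes can share a peak, as Cpr62Ba and Cpr62Bb shared a CP190 peak (42.3-fold). The p-values of these lists may therefore be too small. A gene shorter than 1000 bp is searched over fewer bases than a longer one, since the 500 bp windows at its 2 ends overlap. This holds for tRNA genes such as tRNA:Gln-CTG-4-1, at 14010565 to 14010636 of 2L. Gene length was not held equal, so the lower tRNA share cannot be told apart from an effect of length. Members with a high CP190 peak were Gr89a (29.0-fold) and Or92a (16.3-fold), Cpr97Ea (47.3-fold) and Cpr49Ae (47.2-fold), and tRNA:Gln-CTG-4-1 (62.0-fold). Pita was near 1 chemoreceptor gene in larvae, Ir21a (6.20-fold), and 4 in adults, led by Or63a (3.68-fold), with odds ratios of 0.0474 and 0.181 (adjusted Fisher exact p = 2.17e-06 and 2.41e-04). For cuticle genes Pita gave odds ratios of 0.296 in larvae (4 genes, adjusted Fisher exact p = 0.0368) and 0.206 in adults (3 genes, adjusted p = 0.00788), and the highest peak lay at the facing ends of Cpr62Ba and Cpr62Bb (4.81-fold and 6.49-fold). Of the cuticle genes counted 1, Cpr, which was near CP190 and adult Pita, is in the list by its symbol and encodes no cuticle protein. Without it 21 of 118 cuticle genes were near CP190 (0.388, adjusted Fisher exact p = 3.04e-04) and 2 near adult Pita (0.137, adjusted p = 0.00166), while for larval Pita the odds ratio was 0.298 and missed the threshold (adjusted p = 0.0501), in a setting chosen after seeing the data. The larval Pita value also missed it within 1000 bp (0.529, adjusted Fisher exact p = 0.298) and, in another setting chosen after seeing the data, at an IDR of at most 0.01 (0.313, adjusted p = 0.0646). For tRNA genes Pita did not pass (adjusted Fisher exact p = 0.225 in larvae and 0.397 in adults).

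Su(Hw) showed other gene groups. It lay near 8 of 20 synaptic and neuronal genes in larvae (40.0% against 8.42%, odds ratio 7.25, adjusted p = 0.00130) and 7 in adults (35.0% against 7.19%, 6.95, adjusted p = 0.00308), by Fisher's exact test. The larval peaks were led by Rbp9 (24.2-fold), nSyb (22.5-fold), which encodes the synaptic vesicle SNARE synaptobrevin, VAChT (18.0-fold), the vesicular acetylcholine transporter, and Rim (6.98-fold). In adults VAChT (21.8-fold), nSyb (19.2-fold), Rim (8.95-fold) and Syt1 (7.26-fold) were highest. Cuticle genes were more often near Su(Hw), with 20 of 119 in larvae (odds ratio 2.21, adjusted Fisher exact p = 0.0156) and 19 in adults (2.47, adjusted p = 0.00788). Cpr47Ea (35.7-fold in adults), Cpr47Ee (18.2-fold in larvae and 35.0-fold in adults) and Lcp65Ag3 (15.9-fold and 22.0-fold) led them, and 1 peak can serve neighbouring genes of such clusters. None of the 73 mitochondrial ribosomal protein genes was near larval Su(Hw) against 8.51% of other genes (odds ratio 0.0731 with 0.5 added to each cell, adjusted Fisher exact p = 0.0156). At or above the median −log10 q the synaptic genes no longer passed in larvae (4.72, adjusted Fisher exact p = 0.135) or adults (2.51, adjusted p = 0.700), nor did the mitochondrial ribosomal protein genes in larvae (0.127, adjusted p = 0.364). In all 16 of 91 tests passed, 8 in each direction, and 19 passed adjusted over the list alone. Of the 16 tests 10 passed at or above the median −log10 q. No list passed for CTCF at either stage, where 2 of the 26 unadjusted Fisher exact p-values were under 0.05, both for chemoreceptor genes. The Hox, segmentation, insulator protein, larval serum protein, chorion, vitelline and yolk, and proteasome lists passed for no peak list at 500 bp. Within 1000 bp 3 further tests passed, for chemoreceptor genes with larval CTCF (0.174, adjusted Fisher exact p = 0.0137), mitochondrial ribosomal protein genes with adult Su(Hw) (0.0612, adjusted p = 0.00733) and chorion, vitelline and yolk genes with adult Su(Hw) (4.19, adjusted p = 0.0421).

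The 2 Hox complexes, which hold the genes that set segment identity, were examined in full. Between the outer ends of Ubx and Abd-B, bases 16656623 to 16972236 of 3R, there were 8 CP190 peaks, 12 larval and 9 adult CTCF peaks, 5 larval and 4 adult Pita peaks and 2 Su(Hw) peaks at each stage. CP190 was highest at 16868951 to 16869806, inside lncRNA:iab8 and MSAmiP (57.0-fold), with adult CTCF (186-fold) and Pita in larvae (11.0-fold) and adults (39.5-fold) at the same place. The next was inside Abd-B at 16969323 to 16970391 (54.5-fold), with adult CTCF (201-fold) and larval Pita (63.2-fold), and neither place had a larval CTCF peak. The highest larval CTCF peak lay between Ubx and abd-A at 16798274 to 16799466 (118-fold) with larval Su(Hw) (46.5-fold) and Pita (18.1-fold), adult peaks of all 3 proteins and no CP190 peak. The highest adult Pita peak lay in lncRNA:iab8 (43.2-fold), at 16898323 to 16900037. From lab to Antp, bases 6661427 to 6999228, there were 12 CP190, 7 larval and 5 adult CTCF, 7 larval and 9 adult Pita, and 2 larval and 3 adult Su(Hw) peaks. Pita was highest inside pb (20.5-fold in larvae, 86.5-fold in adults). Larval CTCF (171-fold) and Su(Hw) (22.5-fold) were highest inside Antp, where adult Su(Hw) (25.2-fold) was highest too, and CP190 (53.9-fold) and adult CTCF (251-fold) at the bcd site. The CP190 and CTCF lists are among those whose −log10 IDR fell at their strongest peaks.

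**Figure D4:**
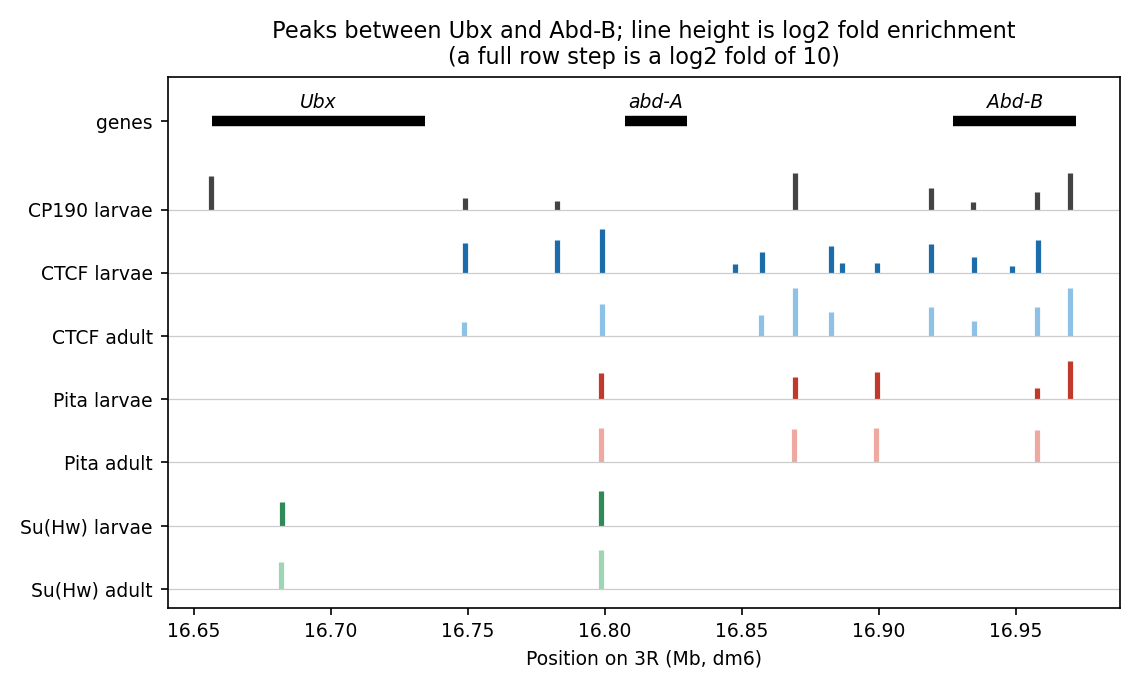
Map of the region from Ubx to Abd-B on 3R (x axis, Mb, dm6), with 1 row per peak list and the spans of 3 Hox genes on top. Line height is the log2 fold enrichment within a list, and the site between Ubx and abd-A holds larval CTCF (118-fold), Pita and Su(Hw) at both stages with no CP190 line.

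The genes of the studied proteins carried their own peaks in part. Pita bound within 500 bp of an end of pita, with a peak of 10.8-fold in larvae, at 23553882 to 23554750 of 2R, and 45.1-fold in adults, together with CP190 (7.95-fold). Su(Hw) bound at an end of su(Hw), with a peak of 44.6-fold in larvae, at 14306671 to 14308642 of 3R, and 67.3-fold in adults, together with CP190 (17.6-fold). At the gene CTCF there were low larval peaks of CTCF (2.46-fold) and Su(Hw) (2.49-fold). No peak of the 7 lists lay within 500 bp of an end of Cp190.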

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

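The strength classes, the splits of sites by nearness to a gene end and by rank of fold within a list, the comparison of partner lists by their IDR, the search beside the overlap and the comparison of overlapping with other peaks in both lists of a pair are tests chosen only after results were seen.

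Peaks outside the main chromosome arms took part in no comparison, and no control sample was used for them. There were 6 in the CP190 list, 16 and 6 in the adult and larval CTCF lists, 7 and 5 in the adult and larval Pita lists, and 4 each in the adult and larval Su(Hw) lists. The highest CP190 peak among them, 16.1-fold, lay at bases 11535 to 12532 of an unlocalised sequence of the Y chromosome. Adult CTCF (2.55-fold), larval CTCF (2.34-fold) and larval Su(Hw) (3.57-fold) had peaks at the same place. A larval Pita peak of 10.8-fold lay at 1355 to 1847 of the same sequence, with peaks of CP190 (5.86-fold), adult CTCF (2.69-fold) and larval CTCF (4.18-fold). Neither place was particular to 1 protein. An adult Pita peak of 9.42-fold covered bases 3 to 1531 of the mitochondrial genome.

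The higher share of CP190 at sites with 2 or 3 C2H2 proteins could come from stronger peaks, wider merged sites or nearness to gene ends. Each of these predicts that the odds ratio of 5.79 goes once it is taken out. It was 2.53 within quartiles of fold (95% interval 1.93 to 3.32) and 2.99 within quartiles of the rank of fold in its own list (2.29 to 3.91). It was 5.74 with summits within 200 bp (4.33 to 7.60) and 4.30 within sites near and away from gene ends (3.33 to 5.54). Taken out separately and in these classes, neither strength nor nearness to gene ends removed it, although strength goes with part of it. With summits within 200 bp, peaks were still joined into sites, and any peak of a site could give it CP190. More peaks thus still gave a site more chances, so this setting could not take out wider merged sites, which stay open. The 3 explanations were not taken out together, and strength that differs within a quartile was left in. The mix of proteins was left in these pooled odds ratios too. Of the 4574 sites used as the comparison, 3150 were Su(Hw)-only sites, with CP190 at 32.0% of them. Pairs set against their own members within quartiles of fold gave odds ratios from 1.54, which did not pass, to 9.81. Recruitment by several proteins together is a hypothesis that stays open, since no list is named for mutant larvae, the CP190 list has no stated genotype and may hold them, and 4 of the 6 tests of pairs against their members did not pass among the more significant peaks.

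The overlap of the C2H2 lists could come from a shared place near gene ends, or from weak signal of 1 protein at strong sites of another. With relocations matched on the distance to a gene end, the lowest ratio over the 3 pairs was 2.25, for Pita and Su(Hw), above the highest matched relocation. Weak signal predicts overlapping peaks that are lower than the others in one list of a pair and higher in the other list, so a higher level in both lists goes against it. CTCF and Su(Hw) showed that, with differences in median log2 fold of 1.71 in the CTCF list (two-sided permutation p = 6.20e-04) and 0.61 in the Su(Hw) list (p = 6.00e-05), so weak signal does not account for that overlap as a whole. For CTCF and Pita the differences were 0.29 in the CTCF list (permutation p = 0.409) and 1.17 in the Pita list (p = 1.00e-05, the smallest possible). For Pita and Su(Hw) they were −0.024 in the Pita list (permutation p = 0.906) and 0.93 in the Su(Hw) list (p = 1.00e-05). In both of these pairs 1 list was neither higher nor lower past the threshold, and weak signal stays open. Binding side by side remains a hypothesis, and open chromatin away from gene ends was not tested.

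The strongest peaks often lacked a partner in another list, as at nAChRalpha5, Rala and bcd. A candidate explanation is that the strongest peaks are missing from partner lists whose −log10 IDR falls at the top. It predicts a larger fall in partnered share, from the ninth to the strongest class, against such lists than against other lists for the same protein. For Pita the mean fall was 18.0 percentage points larger, from 3 comparisons with such lists and 1 with another. For Su(Hw) the difference was −13.6 points, from 2 comparisons of each kind, as its share with CP190 rose. CTCF had no comparison with another kind of list, and its 4 falls against such lists ranged from 2.47 points, for larval peaks in the adult list, to 29.4 points, for adult peaks in the larval list. With 1 protein each way, the explanation stays open. The fall of the IDR is over peaks ranked by −log10 p in the first input list, and that of the partnered share over peaks ranked by fold. Over the 7 comparisons with a fall, the strongest class gave 160 cases of a peak without a partner in a list. Partner peaks just beside the overlap were found within 1000 bp in 3.13% of them (exact 95% interval 1.02% to 7.14%), too few to account for the pattern. A peak can count against 2 partner lists, and the interval takes the cases as independent. A difference in binding between stages or proteins at these sites stays open and was not tested.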

How the results depend on the processing

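Settings named here as added are tests chosen after the data were seen: an IDR of at most 0.01 in every list, lists without their strongest 10%, sites split by nearness to gene ends or by rank of fold within a list, gene lists without Cpr and Vmat, and all tests of pairs of proteins against their members. Over 37 results and 14 settings 248 alternative values were computed, 144 planned and 104 added, and 211 kept their direction and side of the threshold or stayed within their interval. Values for gene ends and gene lists under planned settings count here as planned. Their distance to a gene end replaced the planned distance to a transcription start after the data were seen. The cause of the changes between settings was not tested.

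With lists of equal length the odds ratio of CP190 at CTCF-only against Su(Hw)-only sites reversed to 0.638, that of an adult partner for Su(Hw) against CTCF was 1.32 and no longer passed, and that of CP190 at Su(Hw) peaks of both stages against larva-only peaks was 1.01. Among the more significant peaks of each list, tests no longer passed for CTCF and Pita against CTCF-only (1.95) and Pita-only sites (1.11), CTCF and Su(Hw) against CTCF-only sites (1.34), Pita and Su(Hw) against Pita-only sites (1.31), the strength of Pita peaks with CP190 (a log2 difference of 0.19) and gene ends near CTCF peaks with CP190 (1.43), and 10 of the 16 gene list tests passed. The 6 lost were replication, cuticle protein and tRNA genes with CP190, synaptic genes with Su(Hw) at both stages, and mitochondrial ribosomal protein genes with larval Su(Hw). CTCF and Su(Hw) against CTCF-only sites also missed the threshold on autosome arms (1.80) and within quartiles of fold (1.54). The odds ratio of an adult partner for Su(Hw) against Pita, 1.19 and not past the threshold, turned to 0.919 on autosome arms, 0.450 among the more significant peaks (adjusted Fisher exact p = 5.81e-07), 0.809 with equal lengths, 0.651 at an IDR of 0.01 and 0.972 without the strongest 10%.

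Some results that passed under every alternative moved in size. The odds ratio of CP190 at sites with 2 or 3 against 1 protein ranged from 2.53 within quartiles of fold to 10.0 without the strongest 10%. That of CP190 at peaks of both stages ranged from 1.80 to 3.83 for CTCF and from 2.61 to 4.10 for Pita. That of Pita-only sites ranged from 1.71 to 4.31 against CTCF-only and from 2.75 to 6.70 against Su(Hw)-only sites. For Pita and Su(Hw) sites against Su(Hw)-only sites it went from 8.74 among the more significant peaks to 24.9 without the strongest 10%.

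Stage shares moved beyond their intervals. Among the more significant peaks they were 75.7% and 91.4% for larval and adult CTCF, 92.3% and 75.0% for Pita and 84.3% and 91.5% for Su(Hw). With equal lengths they were 79.7% and 80.4% for larval and adult CTCF, 86.7% for adult Pita, and 83.8% and 84.1% for Su(Hw). At an IDR of 0.01 they were 88.7% for larval Pita, and 83.7% and 95.6% for larval and adult Su(Hw). On autosome arms adult Pita gave 66.1% and larval Su(Hw) 85.7%, and without the strongest 10% they gave 66.5% and 85.4%. With summits within 200 bp larval and adult Su(Hw) gave 85.3% and 92.4%.

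No paired analysis was possible because the lists hold no values per replicate, so leaving out replicates and a replicate block were not run. The sequence words of 6, 7 and 8 bases were not run either. Depth per sample is unknown, so list lengths cannot be set against it.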

Other observations

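The counts and the test here were chosen only after results were seen. CP190 peaks without any larval C2H2 peak lay mostly at gene ends. Of these 2012 peaks 87.2% had the summit within 500 bp of a gene end, against 55.9% of the 2208 peaks with 1 or more C2H2 proteins, an odds ratio of 5.38 (95% interval 4.61 to 6.29, two-sided Fisher exact p = 3.75e-116). The highest of them lay near CG10418 (62.6-fold, bases 12336080 to 12337075 of 3L), mtSSB (62.0-fold), which encodes the single-stranded DNA binding protein of mitochondria, LPCAT (57.9-fold), bcd (53.9-fold) and CG7985 (53.6-fold). The bcd site held an adult CTCF peak of 251-fold and no larval one, and the larval CTCF list is among those whose −log10 IDR fell at the top.

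Ribosomal protein genes near Pita were nearly all near CP190 as well. Of the 29 cytoplasmic ribosomal protein genes near a larval Pita peak 28 were also near a CP190 peak. Another 46 were near CP190 and not near Pita, and 41 genes were near CP190 with no larval peak of the 3 C2H2 proteins. Of all 93 cytoplasmic ribosomal protein genes 74 (79.6%) were near CP190. Whether those near Pita differed from the rest was not tested.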
